A study of Mus musculus with 8 samples.

How the data were processed

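RNA sequencing was done on mouse tracheas and on sorted tracheal cells from embryonic day 13.5. Whole tracheas came from 1 library with Wls deleted by Shh-Cre and from 2 libraries of floxed controls without Cre, per the labels. Sorted cells came from tracheas with Bmp4 deleted (2 libraries) and from floxed controls without Cre (3 libraries). Per the labels, epithelial cells were removed by an antibody to EPCAM and muscle cells by a GFP reporter of smooth muscle gamma-actin, so the sorted cells are those negative for both. They are called chondroblasts below because the labels do so. The labels do not say whether libraries of a group came from separate embryos or litters. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Other data that the series design mentions were not analysed here.

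The deposited values were whole-number counts per gene, 1 table for the sorted cells and 1 for the tracheas, with 23478 gene symbols in each, and they were used as the authors deposited them. The submitters' processing notes name Bowtie2, Cufflinks, DESeq and the mouse build mm10, and for the sorted cells also Trim Galore, with no versions and no roles. The program that made the counts, its strand setting and the gene annotation are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and genes with near-identical copies can share reads. Per the labels' protocols, RNA was isolated with Trizol. Sorted cells were amplified with a SMART-Seq v4 low-input kit, tracheas with an Ovation v2 kit, and both were made into Nextera XT libraries. The kits and the kind of sample differ between the tables, so no library of one table was tested against a library of the other. Receptor sums of both tables are shown side by side without a test. The floxed genes are deleted in part of their exons and in part of the cells, so their counts may include undeleted exons and undeleted cells.

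Library totals were 12964287 and 15462780 counts in the Bmp4 mutants and 55492747, 48876948 and 49714047 in their controls. They were 24596836 counts in the Wls mutant and 27237573 and 31399982 in its controls. Reads carry no molecular identifiers, so counting precision is an upper limit on the precision of each value. Replicate pairs differed by 24.5 to 193 times the variance of counting noise (chi-square per degree of freedom), and every library was counted on its own.

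Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, its default expression filter by group and the quasi-likelihood F test, with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p below comes from this edgeR test unless another tool is named. The standard error of a log2 fold change was taken from the fold change and the F statistic. CPM values of single genes carry the TMM factors, and summed CPM values of gene lists or receptor genes do not. The chondroblast comparison had 3 residual degrees of freedom. The trachea comparison had 1, and its single mutant library was assumed to vary like the 2 controls. For that reason a rule of size without a test was used beside it. It takes genes with an absolute difference of at least 1 in log2 CPM (prior count 2), a mutant value outside the range of the controls by more than the controls differed, and a mean log2 CPM of at least 3. Each control was also put in the role of the mutant.

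Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists with at least 5 tested members. With this preset camera takes its p from the spread across genes, not between libraries, and a higher true correlation makes that p too small. In the deposited counts of the sorted cells, estimated correlations were 0.47 for G2/M, 0.51 for ribosomal and -0.025 for BMP target genes. The same test with a correlation estimated from the data and the rotation test fry were alternatives. With an estimated correlation camera takes its p from the residual degrees of freedom, 3 for the sorted cells and 1 for the tracheas. So few leave it almost no power after adjustment, so its high p-values count neither for nor against a list. The 33 lists were cartilage, smooth muscle, Wnt beta-catenin targets, Wnt ligands and receptors, BMP targets, BMP ligands with receptors and antagonists, Hedgehog, FGF, Notch, TGF-beta and retinoic acid pathways, tracheal mesenchyme transcription factors, fibroblast and perichondrial matrix, G2/M cell cycle, DNA replication, p53 targets, hypoxia and glycolysis, unfolded protein response, interferon response, dissociation and immediate early genes, ribosomal proteins, sex-linked genes and markers of other cells. These markers covered airway epithelium, neurons and neural crest, endothelium, leukocytes, erythroid cells, skeletal muscle, pericytes, mesothelium, thyroid with thymus and parathyroid, lung bud and oesophagus. Lists share members: Des is in both muscle lists, and Sox2 and Trp63 are in the lists of airway epithelium and oesophagus. Sox9, Tbx4 and Tbx5 of the lung bud list are also expressed in tracheal mesenchyme. The ribosomal list was taken by gene symbol and also holds pseudogenes and kinases such as Rps6ka3.

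Genes were named by a rule. It takes a fixed panel, the 10 genes with the largest change in each direction among those past the test with a mean log2 CPM of at least 3 and every mutant library beyond every control (for the tracheas, among those past the rule of size), and up to 4 members with the smallest p of each list. Samples, tests, lists, this rule and the alternatives were chosen before the data were examined, except those named next. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

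A uniform background was found in the Bmp4 mutant libraries and led to alternatives chosen after seeing the data. Exon lengths came from GENCODE M21 on GRCm38, the assembly that mm10 names, matched by gene symbol (93.0% of the genes had a length). The mean count per kilobase of exon over 4085 genes with at most 3 counts in all controls together and at least 500 bp of exon was multiplied by each gene's exon length and subtracted from every library. Only genes with a mean CPM, over mutants and controls together, above the 95th percentile of this background for their length (4.49 CPM per kb) were then tested, which left 9185 genes. The values are called background-subtracted below, and the top 10 genes of this test in each direction were named as well. Further alternatives of this kind tested these genes without subtraction, took scaling factors from them, thinned the controls to the depth of the mutants, removed the erythroid list and combined subtraction with leaving out each library. Two-sided Fisher's exact tests were used for overlaps. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, size factors of the RLE kind, no filter and a stricter filter (CPM of at least 1 in every library of a group), a threshold of 0.1, the replicate number as a block and each library left out in turn. With 1 mutant left, that mutant was assumed to vary like the controls. Leaving out a trachea control leaves no residual degrees of freedom, so it gave fold changes only.

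The tests were tested on simulated data drawn from the libraries' means with 200 changed genes. For the chondroblasts (16275 genes tested) 36% of genes raised 2-fold, 98% raised 4-fold, 50% lowered to 0.5 and 88% lowered to 0.25 were recovered, with 7 false calls. For the tracheas (15571 genes tested) 88%, 100%, 88% and 100% were recovered, with 9 false calls. Genes were drawn independently, and the simulated trachea mutant had the dispersion of the fit, which the 2 controls set. These false calls are therefore no error rate for the real single mutant. With the measured background added to the simulated chondroblast mutants (22188 genes tested) the test called 8334 unchanged genes higher and 1574 lower. After subtraction (11678 genes tested) it called 3 unchanged genes higher and 5 lower and recovered 54%, 100%, 56% and 100%. The added background was exactly in proportion to exon length, the form that was then subtracted. The changed genes were abundant ones above the background. These rates therefore do not carry over to a background that is uneven between genes or to less abundant genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.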

Results

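Gene expression was measured by RNA sequencing in 8 libraries from mouse embryos at E13.5, the embryonic day when the mesenchyme around the airway epithelium separates into cartilage in front and the trachealis muscle behind. In the first experiment Wls, which carries Wnt proteins to the cell surface for secretion, was deleted from the Shh-expressing airway epithelium, and whole tracheas were profiled from 1 mutant and 2 controls. In the second, Bmp4, a secreted growth factor of the BMP family, was deleted, and cells negative for EPCAM and for the muscle reporter were sorted from 2 mutants and 3 controls. Depth was 24596836 counts in the Wls mutant and 27237573 and 31399982 in its controls. It was 12964287 and 15462780 counts in the Bmp4 mutants and 55492747, 48876948 and 49714047 in their controls, so the mutants of the sorted cells were the shallower libraries.

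The sorted cells address what Bmp4 controls in tracheal cells left after removal of epithelium and muscle by the sort. In these libraries fibroblast and perichondrial matrix genes summed to between 12235 and 25728 CPM and cartilage genes to between 1231 and 8093 CPM. Bmp4 itself (mm10, chromosome 14, 46383520 to 46390669) fell from 124, 99.2 and 121 CPM in the 3 controls to 24.1 and 32.2 CPM in the 2 mutants, a log2 fold change of -2.03 ± 0.20 (SE) with edgeR's adjusted p = 0.0033. Msx2, a homeobox gene induced by BMP signals, fell from 55.2 ± 7.86 CPM (SD, n = 3) to 2.92 and 6.80 CPM (log2 fold change -3.49 ± 0.38, adjusted p = 0.0033). The cartilage regulator Sox9 (chromosome 11, 112782224 to 112787760) and the cartilage collagen gene Col2a1 (chromosome 15, 97975602 to 98004695) also fell, with log2 fold changes of -1.99 ± 0.56 (adjusted p = 0.021) and -2.51 ± 0.53 (adjusted p = 0.0068). Smooth muscle myosin, Myh11 (chromosome 16, 14194535 to 14291372), rose from 2.12 ± 1.14 CPM to 192 and 44.5 CPM (log2 fold change 5.80 ± 0.71, adjusted p = 0.0033). The mutants differed from each other for the muscle and cartilage genes: Acta2, smooth muscle alpha-actin, stood at 630 CPM in mutant 1 and at 83.9 CPM in mutant 2 against 52.4 ± 12.5 CPM in controls, and Sox9 at 162 and 469 CPM against 1256 ± 623 CPM. Without mutant 1, Sox9 was at -1.43 (adjusted p = 0.10) and Acta2 at 0.66 (adjusted p = 0.13), and limma-voom gave Acta2 an adjusted p = 0.098 and Actg2 0.092.

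Both mutant libraries also held counts in genes that were near 0 in the controls. The 1456 olfactory and vomeronasal receptor genes, which are active in sensory neurons of the nose, summed to 2455 and 2203 CPM in the mutants and to 11.5, 14.8 and 10.9 CPM in the controls, a mean 188-fold higher. Of the 1055 receptor genes tested, 1043 were called higher in the mutants and 0 lower. Only 919 and 955 genes had no count in the mutants, against 6080, 5661 and 5573 in the controls. Over 4085 genes silent in the controls, the mutants carried 22.1 and 20.3 counts per kilobase of exon, and this rate applied to all exons makes up 11.2% and 8.66% of their counts. In the tracheas the receptor sums were 75.5 CPM in the Wls mutant and 61.9 and 80.9 CPM in its controls.

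**Figure D1:**
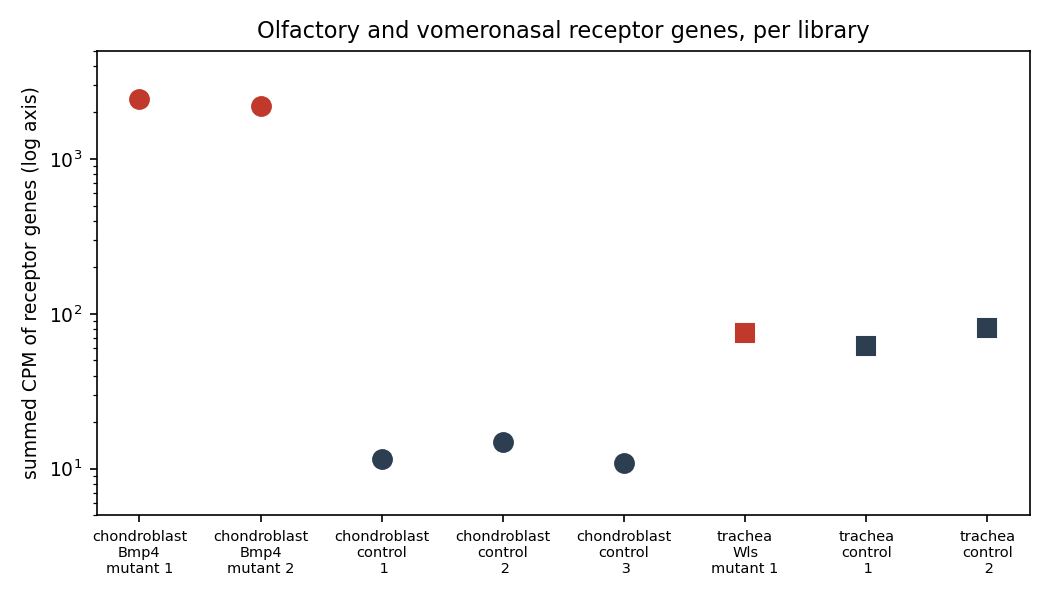
Summed CPM of the olfactory and vomeronasal receptor genes in each library (log axis), with mutants in red, controls in a dark colour, sorted cells as circles and tracheas as squares. The 2 Bmp4 mutants sit at 2455 and 2203 CPM and the other 6 libraries between 10.9 and 80.9 CPM.

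With the counts as deposited, 11888 of 21665 genes passed the test in the Bmp4 mutants, 8507 higher and 3381 lower. The count was 3595 without mutant 1 and 7829 without mutant 2. With scaling factors from genes above the background the split was 9876 higher and 787 lower, and the median log2 fold change of all genes moved from 0.53 to 0.92. Genes above the background had a median of -0.39 in the deposited counts, so fold changes of abundant genes stand relative to that shift. The background-subtracted test called 69 of 9185 genes, 46 higher and 23 lower, and all 69 had the same direction in the deposited counts. Of the 46 higher genes, 18 had a mean of under 1 CPM in the controls. Such genes reached the background limit mainly through the mutants, since the limit was set on the mean of all libraries. For them a local excess of background cannot be told apart from expression. The count of 69 depended on single libraries. It was 0 without mutant 1, 185 without mutant 2, 0 without control 1, 1 without control 2 and 0 without control 3, with 2171, 2766, 1323, 1450 and 1474 genes at an unadjusted p under 0.05 by edgeR. On simulated data with an exactly even background, the subtracted test recovered 54% of abundant genes raised 2-fold.

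After subtraction the targeted gene was among the 23 lower genes. Bmp4 had a background-subtracted log2 fold change of -1.64 ± 0.18 (adjusted p = 0.0476). Sp7, a transcription factor of bone-forming cells, was at -3.24 ± 0.39, and Hmga2, a chromatin protein of growing embryonic tissue, at -3.03 ± 0.35, both with adjusted p = 0.0476. Sox6, a partner of Sox9 in cartilage, was at -1.19 ± 0.15 (adjusted p = 0.0476). Other lower genes were Snx22, Spsb4, Akap2, Spsb1, Synpo, Aif1l and the cadherin gene Fat1, between -2.64 and -1.41. The higher genes were led by 4933438K21Rik with 10.28 ± 0.66 and controls at or under 0.0441 CPM, then Myh11 with 6.29 ± 0.87, Pm20d2 with 5.27 ± 0.43, Pnpla3 with 4.05 ± 0.41 and Sfi1 with 3.49 ± 0.29. Both 4933438K21Rik and Myh11, low in the controls, entered this test through their mutant values. Sfi1 has near-identical copies, so its value is uncertain. Smoc2 and Lrrc32 were higher by 2.35 ± 0.30 and 2.31 ± 0.30, Slc40a1, the iron exporter of macrophages and other cells, by 2.28 ± 0.28, Fam227a by 3.07 ± 0.42 and the stress gene Nupr1 by 2.46 ± 0.33. In this test Sox9 had a log2 fold change of -1.50 (adjusted p = 0.19), Col2a1 of -2.05 (adjusted p = 0.11), Msx2 of -4.24 (adjusted p = 0.10), Acta2 of 3.38 (adjusted p = 0.096) and Actg2 of 4.78 (adjusted p = 0.075), so their calls ended while their directions stayed. Without mutant 1 or mutant 2 Acta2 was at 1.10 or 4.24, Actg2 at 1.91 or 5.70 and Msx2 at -3.34 or -14.0. Sox9 was then at -0.97 or -2.35 and Col2a1 at -1.47 or -3.04. All 69 calls depended on mutant 1 and on each control: the adjusted p of Bmp4 was 0.11 without mutant 1, 0.14 without control 1, 0.085 without control 2 and 0.17 without control 3. Without mutant 2 the adjusted p was 0.059 for Sp7 and Synpo, 0.056 for Fat1, 0.055 for Smoc2 and 0.052 for Akap2 and Nupr1. With that library left out 11 of the 23 lower calls were shared.

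**Figure D2:**
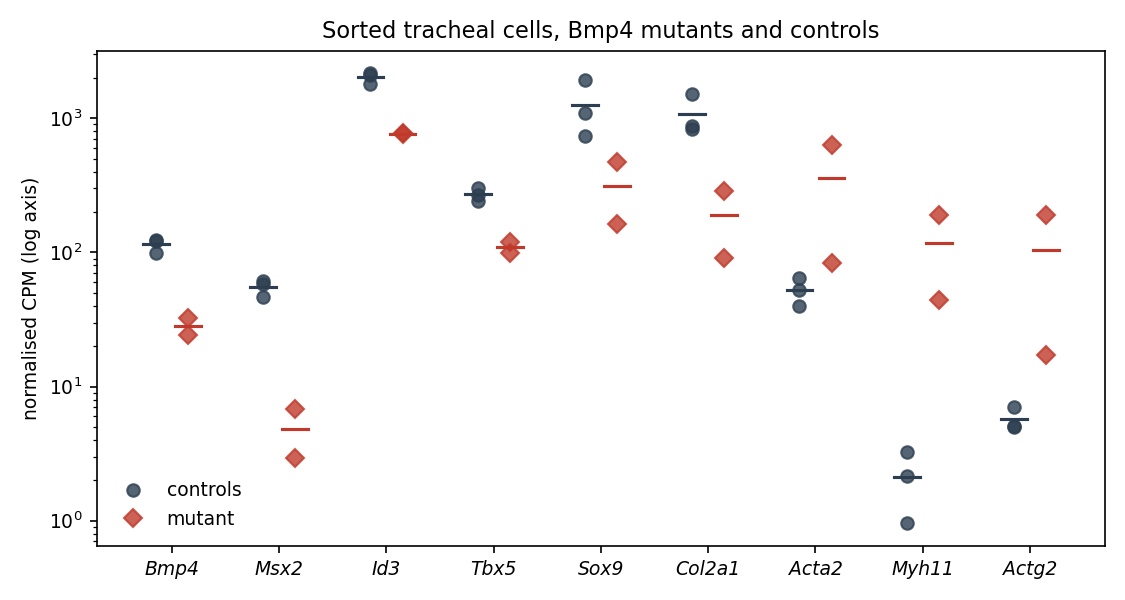
Normalised CPM (log axis) of 9 genes in the sorted cells, with 3 controls as dark circles and 2 Bmp4 mutants as red diamonds, each point a library and each short line a group mean. Bmp4 lies at 24.1 and 32.2 CPM in the mutants and between 99.2 and 124 CPM in the controls, and Myh11 at 192 and 44.5 CPM against at most 3.24 CPM.

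Lists of BMP signalling and of mesenchymal transcription factors were lower in the deposited counts. Camera set each list against all genes tested, whose median of 0.53 carries the background, while genes above it had -0.39. Of the 3381 lower calls 3144 were genes above the background, of which 9185 were tested after subtraction. A list of abundant genes can thus be called lower without a change of its own, here and in the list calls below. Of 19 BMP target genes, 9 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 7.9e-04, adjusted p = 0.44 with an estimated correlation). Id1, Id2 and Id3, inhibitors of differentiation that BMP signals induce, fell with log2 fold changes of -1.31 ± 0.34, -1.23 ± 0.24 and -1.40 ± 0.20, and Id1 had an adjusted p = 0.11 without mutant 1 and 0.063 without mutant 2. After subtraction they were at -0.80, -0.69 and -0.85 and did not pass (adjusted p = 0.24, 0.16 and 0.070). Among 30 transcription factors of tracheal mesenchyme 12 fell and 2 rose, and the same numbers passed adjusted over the list alone (adjusted p = 1.3e-05, adjusted p = 0.54 with an estimated correlation). Tbx5, Tbx2 and Foxp2, which act in the mesenchyme of the foregut, fell with log2 fold changes of -1.30 ± 0.18, -1.74 ± 0.31 and -1.16 ± 0.22, while Tbx4 at -1.03 (adjusted p = 0.088) and Msx1 at -1.32 (adjusted p = 0.11) did not pass. Tbx4 passed with DESeq2 (adjusted p = 0.0497) and without control 3 (adjusted p = 0.023), and was at -0.62 without control 1. Subtraction left Tbx5, Tbx2 and Foxp2 at -0.83, -1.39 and -0.72, none past the test (adjusted p = 0.064, 0.085 and 0.11). Of 26 BMP ligands, receptors and antagonists 8 fell and 2 rose, or 7 and 2 adjusted over the list alone (adjusted p = 0.014, 0.22 without mutant 1, adjusted p = 0.61 with an estimated correlation), with a median of -0.24 that turned to 0.14 with scaling from genes above the background. Among them was Gdf5, a growth factor of joints and cartilage, at -1.99 ± 0.33 (adjusted p = 0.077 after subtraction). Bmp7 was at 0.19 (adjusted p = 0.52), and the BMP antagonist Nog at -2.26 (adjusted p = 0.044, 0.069 without mutant 1, 0.19 without mutant 2 and 0.11 without control 1). After subtraction the median log2 fold change was -0.69 for 11 BMP targets (adjusted p = 0.040), -0.83 for 21 transcription factors (adjusted p = 0.0012) and -0.10 for 15 BMP ligands, receptors and antagonists (adjusted p = 0.057), with an adjusted p = 0.57 for the targets and the factors and 0.62 for the ligands with an estimated correlation. By fry the subtracted targets and factors each had an adjusted p = 0.22 and the ligands 0.40. By edgeR over all genes 0 of these 11 targets, 0 of the 21 factors and 1 of the 15 ligands (lower) then passed. Adjusted over the list alone, 2 targets were lower, 7 factors lower and 1 higher, and 3 ligands lower. The subtracted call of the BMP targets had an adjusted p = 0.056 without control 2 and 0.098 without control 3, and the ligand list 0.0087 without mutant 2 and 0.016 without control 3.

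The cartilage list held 33 tested genes, of which 10 fell and 7 rose, also adjusted over the list alone (adjusted p = 0.043, adjusted p = 0.73 with an estimated correlation). Its median and test were negative, at -0.64, and its mean was 0.33. The adjusted p was 0.54 without mutant 1, 0.054 without mutant 2 and 0.054 without control 1. The fallers included Sox5 at -1.50 ± 0.19 (adjusted p = 0.060 after subtraction) and Sox6, and the genes that rose included Matn3 and Comp, both extracellular matrix genes, which had means of 0.349 and 0.152 CPM in the controls and did not reach the background limit for their length. Acan, the main cartilage proteoglycan, had a log2 fold change of 0.41 ± 0.91 (adjusted p = 0.72). After subtraction 21 cartilage genes had a median of -1.11 (adjusted p = 1.1e-05, adjusted p = 0.57 with an estimated correlation), with 1 lower over all genes and 5 adjusted over the list alone, and the adjusted p of this subtracted test was 0.055 without mutant 1. By fry the subtracted cartilage list did not pass (adjusted p = 0.26). Summed over the list, cartilage genes made up 1231 and 2932 CPM in the mutants and 8093, 5207 and 4196 CPM in the controls.

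Smooth muscle genes moved the other way. Of 24 genes 10 rose and 1 fell, or 9 and 1 adjusted over the list alone, and the list did not pass against the other genes in the deposited counts (adjusted p = 0.46, and 0.021 without mutant 2). Summed over the list, muscle genes made up 4778 and 2608 CPM in the mutants and 2729, 2677 and 2927 CPM in the controls, so the sum was higher only in mutant 1. Myocd, the master regulator of smooth muscle genes, rose by 2.26 ± 0.36 on the log2 scale, and Lmod1 and Kcnmb1, genes of contractile muscle, by 3.43 ± 0.59 and 3.41 ± 0.66, all 3 under the background limit for their length and so not tested after subtraction. Actg2, the gamma-actin whose reporter was used to remove muscle cells in the sort, was at 190 and 17.1 CPM against 5.69 ± 1.17 CPM (adjusted p = 0.0051), with a log2 fold change of 1.57 without mutant 1. After subtraction 16 muscle genes had a median of 1.12 (camera adjusted p = 4.4e-06, fry adjusted p = 0.24, adjusted p = 0.57 with an estimated correlation). Of them 1 was higher over all genes and 9 adjusted over the list alone. The median was 0.35 without mutant 1. Members low in the controls reached this test mainly through the mutants. Fibroblast and perichondrial matrix genes were higher in the same test by camera, with a median of 0.89 over 27 genes (camera adjusted p = 2.0e-11, fry adjusted p = 0.093, adjusted p = 0.57 with an estimated correlation). Of them 1 was higher over all genes and 17 adjusted over the list alone. Col14a1, a fibril-associated collagen gene, was at 2.08 ± 0.22 (adjusted p = 0.0476), and Mfap5 at 2.86 ± 0.41 (adjusted p = 0.0504) and the matrix proteoglycan gene Dcn at 1.74 ± 0.31 (adjusted p = 0.064) did not pass. In the deposited counts 9 of 29 matrix genes rose and 1 fell, or 5 and 0 adjusted over the list alone (adjusted p = 0.89).

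Genes of growth and metabolism were lower in the deposited counts. There all genes above the background had a median of -0.39, so these falls stand relative to that shift. Of 26 G2/M genes 20 fell and 0 rose, also adjusted over the list alone (adjusted p = 1.3e-08, adjusted p = 0.54 with an estimated correlation). For DNA replication 22 of 32 genes fell, 23 adjusted over the list alone (adjusted p = 3.2e-10, adjusted p = 0.54 with an estimated correlation). Cenpf and Plk1, which act in mitosis, were at -0.93 ± 0.15 and -0.77 ± 0.15, and Pcna and Mcm7, of the replication fork, at -1.03 ± 0.15 and -0.99 ± 0.15. Of 28 hypoxia and glycolysis genes 18 fell and 2 rose, also adjusted over the list alone (adjusted p = 9.7e-07, adjusted p = 0.36 with an estimated correlation), with Pfkl and Eno1, enzymes of glycolysis, at -1.22 ± 0.15 and -1.33 ± 0.17. Of 99 ribosomal genes 73 fell and 3 rose, or 77 and 3 adjusted over the list alone (adjusted p = 7.4e-19, adjusted p = 0.54 with an estimated correlation). After subtraction their medians shrank to -0.23, -0.33, -0.34 and -0.28, with an adjusted p = 0.0091, 0.0017, 0.0036 and 4.8e-05, 0 members past edgeR's test over all genes (adjusted over the list alone 1 G2/M gene lower, and 6 hypoxia genes lower and 1 higher) and an adjusted p between 0.57 and 0.70 with an estimated correlation. The subtracted G2/M call had an adjusted p = 0.15 without mutant 1, and the ribosomal call 0.83 without mutant 2.

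Among signalling lists, 6 of 14 Hedgehog genes fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0022, adjusted p = 0.54 with an estimated correlation), with the effectors Gli1, Gli2 and Gli3 at -1.46 ± 0.21, -0.97 ± 0.15 and -1.08 ± 0.17. Of 16 retinoic acid genes 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0066, adjusted p = 0.45 with an estimated correlation), among them the receptor gene Rarb at -1.38 ± 0.21 and Stra6, the retinol uptake receptor gene, at -1.27 ± 0.18. Both calls had an adjusted p = 0.058 without mutant 1. After subtraction the medians were -0.57 (adjusted p = 0.042) and -0.31 (adjusted p = 0.043), both with an adjusted p = 0.57 with an estimated correlation. By edgeR over all genes 0 of 14 Hedgehog and 0 of 12 retinoic acid genes then passed. When adjusted over the list alone, 4 Hedgehog genes were lower and 1 higher and 5 retinoic acid genes lower. Gli1, Gli2, Gli3, Rarb and Stra6 had an adjusted p = 0.054, 0.075, 0.071, 0.075 and 0.076. The subtracted Hedgehog call ended without mutant 1 (adjusted p = 0.48), control 1 (0.066) or control 3 (0.082). That of retinoic acid ended without mutant 1 (0.29), mutant 2 (0.065), control 2 (0.061) or control 3 (0.053). Of 23 unfolded protein response genes 6 fell, or 2 adjusted over the list alone (adjusted p = 7.9e-04, adjusted p = 0.45 with an estimated correlation). Of 28 dissociation and immediate early genes 3 fell, or 1 adjusted over the list alone (adjusted p = 0.036, adjusted p = 0.83 with an estimated correlation). The last call had an adjusted p = 0.47 without mutant 1, 0.15 without control 2 and 0.075 without control 3. The medians of these 2 lists, -0.37 and -0.24, turned to 0.04 and 0.13 with scaling from genes above the background and to 0.12 and 0.28 after subtraction.

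The Wnt lists did not pass in the sorted cells. Of 19 beta-catenin targets 2 rose and 2 fell, or 1 and 2 adjusted over the list alone (adjusted p = 0.40). Of 33 Wnt ligands and receptors 7 rose and 4 fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.31), with a median of -0.13 that turned to 0.26 with scaling from genes above the background. Lef1, a nuclear partner of beta-catenin, fell with -1.31 ± 0.25, while Axin2 at -0.65 (adjusted p = 0.24) and Notum at -1.67 (adjusted p = 0.13) did not pass. Notum passed without control 3, at -2.14 (adjusted p = 0.017), and was at -0.49 without control 1. Wls was at -1.10 ± 0.26 (adjusted p = 0.010, and 0.068 without mutant 1) and Wnt5a at -1.50 ± 0.50 (adjusted p = 0.038, between 0.052 and 0.20 without mutant 1, mutant 2, control 1 or control 2). After subtraction Lef1, Wls and Wnt5a were at -1.10, -0.67 and -1.09 and did not pass (adjusted p = 0.11, 0.19 and 0.27). Wnt4 and Wnt7b were called higher, by 2.69 ± 0.61 and 3.62 ± 1.30, at 12.5 and 4.25 and at 3.65 and 2.10 CPM, under the background limit for their length, and lost the call without mutant 1 (adjusted p = 0.13 and 0.26). Wnt7b also lost it without mutant 2 (adjusted p = 0.15) and without control 3 (adjusted p = 0.095). The FGF, Notch, TGF-beta and p53 lists had an adjusted p = 0.41, 0.52, 0.23 and 0.13. After subtraction they had medians of -0.31, -0.01, -0.08 and 0.07 and did not pass (adjusted p = 0.068, 0.78, 0.26 and 0.92). In that test FGF was called lower without mutant 2 (adjusted p = 0.010) or control 3 (0.028), and TGF-beta higher without mutant 1 (0.0094). The median of the TGF-beta list turned from -0.04 to 0.33 with the other scaling. For the beta-catenin targets and the FGF, Notch and p53 lists the median was above 0 and the test pointed down, as it did for neurons and skeletal muscle.

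Several lists of markers of other cells were also higher, though not alike in the mutants. After subtraction mesothelium genes summed to 589 and 209 CPM in mutants 1 and 2 and 85.8, 294 and 230 CPM in the controls. Members low in the controls reached the subtracted test mainly through the mutants, since the background limit was set on the mean of all libraries. None of these lists passed fry after subtraction (adjusted p = 0.093 for leukocytes). Erythroid transcripts made up 127590 CPM in mutant 1 and 1426 CPM in mutant 2 against 66.0, 9380 and 9834 CPM in the controls, and the embryonic globin gene Hbb-y, chosen after its values were seen, alone 10.5% of the counts of mutant 1 and at most 0.754% of the others. After subtraction the lists of leukocytes (16 genes, median 0.93, adjusted p = 1.5e-06), endothelium (10 genes, 0.98, adjusted p = 0.0091), neurons and neural crest (19 genes, 0.52, adjusted p = 0.0037), mesothelium (7 genes, 1.79, adjusted p = 0.040), erythroid cells (11 genes, 3.62, adjusted p = 6.7e-04) and interferon response (6 genes, 0.75, adjusted p = 0.040) were higher, with an adjusted p between 0.57 and 0.62 with an estimated correlation. Of these calls leukocytes kept an adjusted p of at most 0.00014 when each library was left out in turn. Without mutant 1 the adjusted p was 0.17 for endothelium, 0.75 for mesothelium, 0.34 for erythroid cells and 0.17 for interferon response. Without mutant 2 it was 0.088 for neurons and 0.055 for interferon response. Without control 1 it was 0.066 for mesothelium and 0.066 for interferon response. Csf1r, the growth factor receptor gene of macrophages, was the leukocyte gene past the test, at 1.26 ± 0.17 (adjusted p = 0.0476). Airway epithelium (6 genes, 0.90, adjusted p = 0.067), pericytes (7 genes, 0.35, adjusted p = 0.38), skeletal muscle (9 genes, -0.31, adjusted p = 0.17) and lung bud (9 genes, -0.40, adjusted p = 0.13) did not pass. Airway epithelium passed without mutant 2 (adjusted p = 0.040), control 1 (0.047) or control 2 (0.024). Skeletal muscle was lower without mutant 1 (1.4e-04) or control 1 (0.049), and without mutant 2 pericytes (0.0498) and lung bud (0.039) passed. In the deposited counts the list of thyroid, thymus and parathyroid genes was the only list that camera called higher (8 of 10 genes, also adjusted over the list alone, adjusted p = 0.031, 0.11 without mutant 1 and 0.066 without mutant 2, adjusted p = 0.61 with an estimated correlation). None of its genes lay above the background: Foxn1, a thymus regulator, was at 7.74 and 3.06 CPM against 0.0277 ± 0.048 CPM. In those counts 14 of 28 airway epithelium genes and 10 of 22 interferon genes rose and 0 fell (adjusted p = 0.091 for each). The oesophagus and sex-linked lists had an adjusted p = 0.40 and 0.68.

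The highest genes of the deposited counts included Dnah5, Fer1l4, Pkhd1, Mroh2a, Csprs, 4933438K21Rik, Fat2, Pkd1l2 and Muc19. Dnah5, a ciliary dynein gene, had 39.5 and 35.8 CPM in the mutants and 0 counts in every control, and of these genes only 4933438K21Rik was tested above the background, Csprs and Muc19 having no exon length. The 10 lowest, after Msx2 and Col2a1, included Ngp, Lcn2 and Ltf, granule genes of neutrophils, whose controls ranged from 53.4 to 334, from 9.22 to 52.1 and from 28.5 to 165 CPM. The others were Hmga2, the slow muscle troponin gene Tnnc1 at -2.95 ± 0.41, and the RNA genes Rpph1, E130012A19Rik and 2610035D17Rik. Ngp, Lcn2, Ltf, Rpph1 and E130012A19Rik lost the call without mutant 1 (adjusted p between 0.082 and 0.13), and Lcn2, Ltf, Rpph1 and E130012A19Rik without mutant 2 (between 0.054 and 0.20).

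The tracheas address what Wnt secretion from the epithelium controls in the whole organ. Wls (chromosome 3, 159839672 to 159938664) fell from 153 and 146 CPM in the controls to 65.8 CPM in the mutant, a log2 fold change of -1.19 ± 0.18 (SE, n = 1 mutant and 2 controls) with edgeR's adjusted p = 2.2e-07. Notum (chromosome 11, 120653788 to 120661175), a secreted Wnt inhibitor that Wnt signals induce, fell from 25.8 and 23.7 to 7.42 CPM (-1.74 ± 0.23, adjusted p = 3.8e-10). Bmp4 fell from 50.7 and 49.1 to 30.9 CPM (-0.69 ± 0.19, adjusted p = 0.011), and Sox9 and Col2a1 fell by 1.28 and 1.57 on the log2 scale (adjusted p = 3.4e-08 and 7.2e-09). Acta2 rose from 733 and 625 CPM by 0.82 ± 0.22 on the log2 scale (adjusted p = 0.011), while Myh11 at 0.57 (adjusted p = 0.10) and Actg2 at 0.32 (adjusted p = 0.46) did not pass. The mutant has no replicate, so the spread comes from the 2 controls alone.

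**Figure D3:**
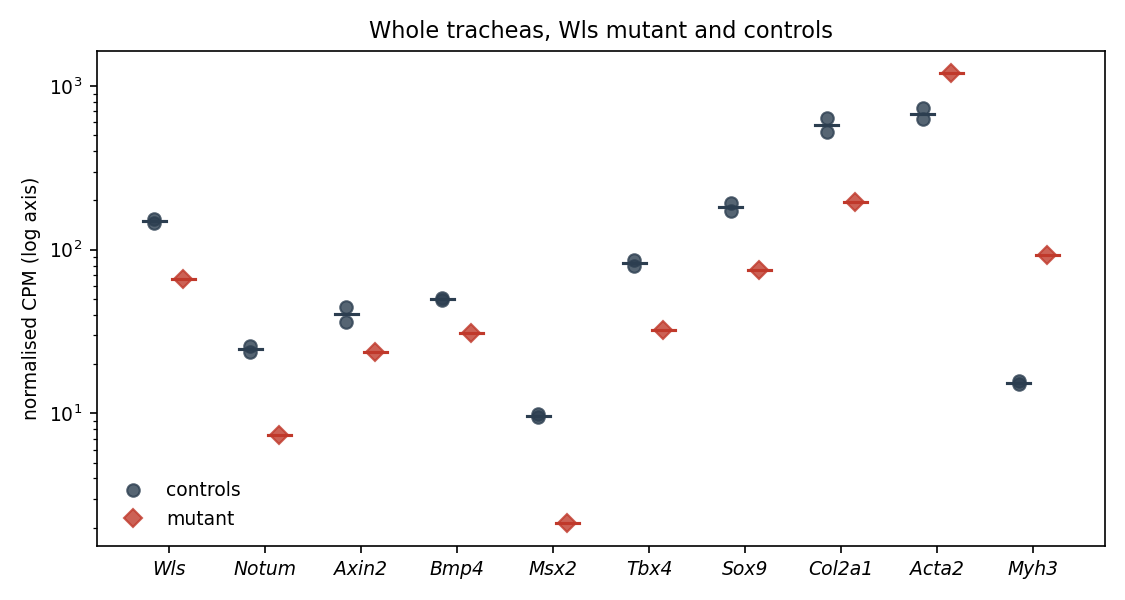
Normalised CPM (log axis) of 10 genes in whole tracheas, with 2 controls as dark circles and the Wls mutant as a red diamond, each point a library and each short line a group mean. Wls lies at 65.8 CPM against 153 and 146 CPM, and Myh3 at 92.4 CPM against 15.7 and 15.1 CPM.

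In all, 676 of 15815 genes passed the test, 298 higher and 378 lower, and DESeq2 called 268, 107 higher and 161 lower. With DESeq2 Bmp4 had an adjusted p = 0.095, Axin2 0.10, Lef1 0.12 and Nog 0.24, and limma-voom gave Nog 0.063. The rule of size took 118 genes, 40 higher and 78 lower, against 2 and 18 genes when control 1 or control 2 stood in the role of the mutant.

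The highest genes by the rule were Myh3, the embryonic skeletal muscle myosin, at 2.58 ± 0.18, Aldh1a1, an enzyme of retinoic acid synthesis, at 2.34 ± 0.18, and Foxf2, a mesenchymal transcription factor that responds to Hedgehog signals, at 1.89 ± 0.20. Next came Ces1d, Irx3, Aldh1a7, Irx5, Cwc22, Crmp1 and Cckar, between 1.88 and 1.59. Cwc22 has near-identical copies and Aldh1a1 and Aldh1a7 are close in sequence, so their values are uncertain. The lowest were the RNA gene AI506816 at -2.90 ± 0.27 and Sned1 at -2.62 ± 0.23. Sned1 had controls of 44.9 and 124 CPM, and AW549542 of 35.5 and 64.7 CPM, with an adjusted p = 0.48 and 0.14 by DESeq2. The fold change of Sned1 was -3.15 without control 1 and -1.70 without control 2, and that of AW549542 -2.45 and -1.59. The other lowest were the cartilage genes Col11a2 at -2.15 ± 0.21, Matn4 at -1.82 ± 0.19, Col9a3 at -1.75 ± 0.19 and Susd5 at -1.97 ± 0.23, the growth factor gene Gdf5 at -1.93 ± 0.22, the receptor gene Lgr6 at -1.90 ± 0.28, and Notum.

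Cartilage genes were lower as a group in the Wls mutant. Of 30 genes 14 fell and 0 rose, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.1e-32, adjusted p = 0.81 with an estimated correlation). Acan fell from 13.9 and 12.5 to 2.21 CPM. Of 30 mesenchymal transcription factors 9 fell and 3 rose, or 9 and 4 adjusted over the list alone (adjusted p = 0.0028, adjusted p = 0.81 with an estimated correlation), with Msx2 at -2.18 ± 0.34, Tbx4 at -1.36 ± 0.19, Tbx5 at -1.08 ± 0.18 and Tbx2 at -1.27 ± 0.20. Of 19 BMP targets 5 fell and 1 rose, or 6 and 2 adjusted over the list alone (adjusted p = 0.029, adjusted p = 0.83 with an estimated correlation), while Id1 at -0.27 (adjusted p = 0.54), Id3 at -0.48 (adjusted p = 0.16) and Msx1 at -0.06 (adjusted p = 0.98) did not pass. Of 26 BMP ligands, receptors and antagonists 7 fell and 3 rose, or 8 and 3 adjusted over the list alone (adjusted p = 0.0048, adjusted p = 0.82 with an estimated correlation). Gdf10, a BMP family member, fell by 1.42 on the log2 scale, Nog fell by 1.01, the antagonist genes Chrdl1 and Fst rose by 1.09 ± 0.17 and 1.42 ± 0.24, and Bmp7 was at 0.09 (adjusted p = 0.89).

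Muscle and epithelial genes were higher. Of 24 smooth muscle genes 8 rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 1.8e-08, adjusted p = 0.81 with an estimated correlation), with Myocd at 0.80 ± 0.18, Casq2, a calcium store protein gene, at 1.41 ± 0.27 and Ldb3 as the faller at -0.90 ± 0.23. Of 26 skeletal muscle genes 13 rose and 1 fell, or 16 and 1 adjusted over the list alone (adjusted p = 1.6e-15, adjusted p = 0.81 with an estimated correlation), led by the myosins Myh3 and Myh8 at 2.58 and 2.24. The summed level of this list was 903 CPM in the mutant and 971 and 737 CPM in the controls. Of 30 airway epithelium genes 12 rose and 2 fell, or 16 and 2 adjusted over the list alone (adjusted p = 8.0e-10, adjusted p = 0.81 with an estimated correlation), with Epcam, the epithelial adhesion gene, at 249 CPM against 142 and 112 CPM, Sox2 at 0.98 ± 0.17 and the basal keratin gene Krt5 as a faller at -1.34 ± 0.25. Shh, made by the epithelium, was at 24.5 CPM against 20.1 and 19.4 CPM (adjusted p = 0.50). Of 21 endothelial genes 4 fell, or 7 adjusted over the list alone, and 0 rose (adjusted p = 1.5e-06, adjusted p = 0.81 with an estimated correlation), among them Eng and Cdh5 at -0.80 ± 0.19 and -0.61 ± 0.18.

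Wnt genes moved both ways. Of 19 beta-catenin targets 5 rose and 5 fell, or 6 and 8 adjusted over the list alone (adjusted p = 0.51, median 0.03, mean -0.11). Axin2, a feedback inhibitor of Wnt signalling, fell by 0.76 on the log2 scale (adjusted p = 0.0046), Lef1 fell by 0.88 (adjusted p = 0.0043) and Wif1, a secreted Wnt inhibitor gene, fell by 1.25. Cyp26a1, which degrades retinoic acid, rose by 1.95 ± 0.33 and Lgr5, a receptor gene, by 1.05 ± 0.24. Of 31 Wnt ligands and receptors 4 rose and 4 fell, or 6 and 6 adjusted over the list alone (adjusted p = 0.49). The epithelial ligand genes Wnt4 and Wnt7b rose by 1.05 ± 0.18 and 0.71 ± 0.17, Wnt2 rose by 1.32 ± 0.21, Wnt5a fell by 0.88 and the receptor gene Ror1 fell by 1.25 on the log2 scale.

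The series title places Bmp4 downstream of Wnt signals, so the sets from the sorted cells were followed in the tracheas. Bmp4, the gene deleted in the sorted cells, was lower in the tracheas by edgeR but not by DESeq2 (adjusted p = 0.095). The 23 genes lower after background subtraction, a set that changes when a library is left out, had a mean log2 fold change of -0.61 in the Wls mutant, with 95.7% of them negative, and 10 of them were also called lower there. Named after their values were seen, they were Sp7, Spsb4, Prdm16, Snx22, Tenm4, Sox6, Thsd4, Synpo, Bmp4 and 6030408B16Rik, with log2 fold changes in the tracheas between -1.75 and -0.67. Independent lists of these sizes would share 0.591 genes (Fisher's exact p = 8.8e-11). Without Bmp4, whose fall in the sorted cells was made by design, 9 of 22 were shared against 0.563 (Fisher's exact p = 1.5e-09), with a mean of -0.61. Both p-values treat genes as independent, which they are not, and the trachea calls rest on 1 mutant. The cartilage list, which holds Sox6, was lower in both experiments by camera, with medians of -1.11 after subtraction and -0.96 in the tracheas. The overlap therefore does not show that Bmp4 acts downstream of Wnt signals, and its cause was not tested. Of the 23 lower calls 0 were shared when control 1, 2 or 3 was left out of the sorted cells, and the calls also depended on mutant 1. Of the 31 higher genes tested in both, 0 were called higher in the Wls mutant by edgeR against 0.366 from independent lists, and their mean was 0.084. The sets from the deposited counts, 3225 higher and 3366 lower genes, had means of -0.027 and -0.026 and were not called by camera, and 135 and 115 of them were called in the same direction against 60.8 and 80.3 from independent lists. Fisher's exact p was 1.8e-22 for the 135 and 2.4e-05 for the 115, though the background was still in these counts. In the opposite direction, 43 genes of the higher set were called lower and 10 of the lower set higher. The 100 lower genes with the smallest p were called lower as a set by camera with its preset correlation, with a mean of -0.22, 19 lower and 0 higher. An estimated correlation was not tried for this set. The 100 such higher genes were not called, with a mean of 0.016, 1 higher and 0 lower. Across all 15798 genes tested in both, which are not independent, the fold changes had a Pearson r of 0.020. Across 9069 genes with the subtracted values the Pearson r was 0.14 and Spearman's rho 0.053.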

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

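The background, thinning, erythroid and above-background tests were chosen only after the results were seen. Of the 57 named genes of the sorted cells, RLE size factors, no filter and thinned controls kept each call. DESeq2 kept 56, the stricter filter 56, limma-voom 46, scaling from genes above the background 54 and the block below 8 (48 lost). Without mutant 1 or 2, 44 and 48 were kept, and without control 1, 2 or 3, 55, 55 and 53. Of 41 tested after background subtraction, 24 kept their side of the threshold and 17 lost it, and when a library was also left out 4 (without mutant 1, control 1 or control 3), 5 (without control 2) and 22 (without mutant 2) kept it. Of the 43 named genes of the tracheas, RLE size factors and no filter kept each call, limma-voom 42, and DESeq2 36 of 42. Leaving out control 1 moved 8 of the 43 fold changes by more than the spread of the controls, and control 2 moved 1. The count of 11888 genes was 69 after subtraction (fewer genes tested and background removed) and 174 in the same genes without subtraction. Leaving out 1 library gave 3595 (without mutant 1) to 10478, and with subtraction 0 (without mutant 1, control 1 or control 3), 1 (without control 2) and 185 (without mutant 2). With the replicate number as a block 4 genes passed, 9833 at an unadjusted p under 0.05. The labels do not say that the numbers pair the libraries. Deviations of replicates 1 and 2 correlated at -0.31 over 11127 genes, a single value over dependent genes that cannot show whether they do. Control 3 was alone in its block. Lists past the test numbered 7 (without mutant 1) to 14 when a library was left out, 12 with the block and 0 with an estimated correlation in both experiments. In the sorted cells fry passed 10 lists, 4 of them higher (interferon, airway epithelium, oesophagus and thyroid with thymus and parathyroid), against 13 and 1 by camera. After subtraction no list passed fry, against 17 by camera, and fry's smallest adjusted p was 0.071, for hypoxia and glycolysis. For the tracheas fry passed 0 lists, against 13 by camera. With 3 residual degrees of freedom in the sorted cells and 1 in the tracheas, an estimated correlation could hardly let a list pass. Its 0 lists, and those of fry in the tracheas, cannot tell a list that moved from one that did not. Acan, never called in the sorted cells, reversed to -0.011 with the block and ranged from -0.15 to 1.54 without single libraries, and Bmp7 from -0.011 to 0.38. In the tracheas DESeq2 gave 268 genes against 676, and the rule of size 367 with a minimum mean log2 CPM of 0. The mean of the higher set in the Wls mutant turned from -0.027 to 0.016 for the top 100 genes and to 0.084 after subtraction, and that of the lower set went to -0.22 and -0.61. The cause of these differences was not tested except where stated. Depth was lower in the Bmp4 mutants, with 12964287 and 15462780 counts, and thinning the controls to it left 10969 genes.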

Other observations

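The tests of explanations in this part were chosen only after the results they concern had been seen, and those on gene positions were prompted by Crmp1 and AI506816, whose values were already known. The bounds of the muscle and position tests were changed after their results were seen. For muscle and other cell types the spread of the controls was added to bounds that every value had met. For positions a p of 0.05 or more was first written as evidence against. It was met around Shh (without the prompting genes) and around Wls. The bound was dropped for Shh, since a p that misses the threshold does not show equal shares. For Wls it stands as written but was not used, since only 0.428 genes were expected there.

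Other groups also moved in the Wls mutant trachea. Ribosomal genes (97 tested, median 0.27, camera adjusted p = 8.0e-10), leukocyte genes (21 tested, 0.41, adjusted p = 6.1e-04) and G2/M genes (26 tested, 0.12, adjusted p = 0.029) were higher as lists, with 0 members past the test in each, and lung bud genes (14 tested, -0.08, adjusted p = 0.029) and sex-linked genes (5 tested, -1.11, adjusted p = 0.0030) were lower. By edgeR 3 lung bud genes were higher and 5 lower, also adjusted over the list alone, and 0 sex-linked genes higher and 3 lower, or 4 adjusted over the list alone. With an estimated correlation these lists had an adjusted p between 0.81 and 0.83. Pax8, a thyroid transcription factor gene, was at 4.22 CPM in the mutant against 0.336 and 0.0622 CPM, and its list of thyroid, thymus and parathyroid genes had an adjusted p = 0.062. The neural crest gene Ret, which marks precursors of airway nerves, rose by 0.77 ± 0.18 (list adjusted p = 0.20). Other lists did not pass: Hedgehog 0.16, FGF 0.93, Notch 0.071, TGF-beta 0.097, retinoic acid 0.20, matrix 0.51, DNA replication 0.82, p53 0.74, hypoxia 0.93, unfolded protein 0.11, interferon 0.98, immediate early 0.64, erythroid 0.74, pericytes 0.89, mesothelium 0.88 and oesophagus 0.74 (adjusted p). Xist, transcribed from the inactive X, was at 99.3 and 38.4 CPM in the Bmp4 mutants and 381, 222 and 244 CPM in their controls, and the Y-linked Ddx3y at 13.4 and 67.0 against 0.108, 41.2 and 34.1 CPM. The mutant values include the background, and Xist has 17946 bp of exon. After subtraction the sex-linked list summed to 89.2 and 143 CPM in the mutants and 381, 300 and 323 CPM in the controls. Ddx3y was near 0 only in control 1. The mix of sexes may differ with genotype, which was not adjusted for. In the tracheas Xist was at 1238 CPM in the mutant and 646 and 1473 CPM in the controls, and Ddx3y at 5.20, 16.4 and 6.34 CPM.

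The first pattern is the large number of genes called higher in the Bmp4 mutant cells. Lower depth of the mutants is argued against, since 8064 genes were still called higher with the controls thinned to their depth. Reads spread evenly over the genome remain a candidate explanation: over genes silent in the controls, the count per kilobase in the longest of 3 length classes was 0.877 and 0.792 times that in the shortest in mutants 1 and 2. In controls 1, 2 and 3, with few counts in these genes, it was 0.048, 0.066 and 0.079 in the shortest class and 0.048, 0.047 and 0.060 in the longest. The ratio therefore does not set the mutants apart from the controls and cannot name a source. Genomic DNA in both mutant libraries stays a hypothesis, found and examined on the same data. A part of the loss of Bmp4 in the pattern stays open and was not tested.

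The second pattern is the higher level of smooth muscle genes in the same libraries, clear in mutant 1 alone by the summed level (5151 and 2703 CPM in mutants 1 and 2 after subtraction, and between 2677 and 2927 CPM in the controls). For mutant 1 an even background is argued against, since after subtraction 16 muscle genes had a median log2 ratio of 1.42 to the controls, where each control set against the other 2 had at most 0.29 (SD 0.41, n = 3). For mutant 2 an even background stays open, since its median of 0.35 lay within that spread. A smaller share of the main cells, which would raise every other cell type alike, also stays open: the highest and lowest medians of 7 other cell types lay 2.19 and 2.84 apart in mutants 1 and 2 and up to 1.88 in the controls (SD 0.26, n = 3), and only mutant 2 exceeded these by more than 2 SD. Muscle cells that passed the sort, which the GFP reporter should remove, cannot be told apart from an effect of Bmp4 loss in the sorted cells, since the sorted mutants are the only ones profiled: 15 of 16 muscle genes in mutant 1 and 9 of 16 in mutant 2 were above every control after subtraction.

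The last pattern lies in the position of the genes that passed the rule of size in the Wls mutant, which carries the Cre at Shh while the controls do not. Within 20 Mb of Shh (chromosome 5, 28456815 to 28467256), the only width tried around it, 6 of 163 genes passed (AI506816, Crmp1, Nos3, Sema3a, Sema3e and Stk32b, 3 of them higher), or 3.68% against 1.04% elsewhere (Fisher's exact p = 0.0086). That count holds Crmp1 and AI506816, which prompted the test, and without them 4 of 161 genes passed, 2.48% (Fisher's exact p = 0.093), so alleles of another strain carried along with the Cre stay open, neither supported nor excluded. Among 73 windows of 40 Mb with at least 20 genes the first of chromosome 5 had the highest share, 6 of 165 or 3.64%, followed by 3.05%, and without the prompting genes it ranked 10 with 2.45%. A difference that also lies around the floxed Wls stays open, since within 20 Mb of it 2 of 40 genes passed (Fisher's exact p = 0.070), with 0.428 expected and Wls itself 1 of the 2, as does an untested effect of Wnt secretion or strain.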
